A study of Mus musculus with 8 samples.

How the data were processed

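Total RNA from mouse liver was extracted with a mirVana kit, and stranded total RNA libraries were made with an Illumina kit, per the labels. The processing notes name Bowtie2 and the mm10 build, and the design text names a NextSeq instrument and Illumina software in BaseSpace. Quantifier, annotation and filters are not given in the sources used here. In 1 of the 2 tables the authors deposited a signal: estimated read counts per gene divided by a normalization factor, by its name a DESeq scaling by the authors. These values are not whole, and only part of the low ones are multiples of 1 step per library, so whole reads were not recovered. The other table the authors deposited holds TPM. After removal of a constant per gene and per library, the log2 ratio of both tables had an SD of 0.00537, so they hold the same estimates with other scaling. Names of 26 genes had turned into dates in the TPM values, and these rows were left out there. Mir6236, a small-RNA locus by its symbol only, held from 0.308% (Null 4) to 89.4% (Null 1) of the TPM. Of the normalized counts, Mir6236 and Rn45s together held at most 5.18% (Null 1). What the reads at Mir6236 stem from was not tested. Both files list 24972 genes and no mitochondrially encoded ones, so a mitochondrial share was not computed.

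The design fixed before the data were examined named a count model first, and limma-trend on log2(value + 1) if no counts were found. The files hold another unit, a signal and not counts, so this fallback was used on the first table, as the authors scaled it. Genes with at least 10 in at least 4 libraries were tested, 13301 in all, a filter chosen after the unit was known. limma 3.58.1 in R 4.3.3 was fitted with a term for group (eBayes with a trend, two-sided), with Benjamini-Hochberg adjustment and a threshold of 0.05. Adding 1 understates changes of genes with low values. Libraries were assigned by column title and numbered by its order within each group, and the numbers pair no libraries. No pair of libraries had identical values in more than 10 tested genes, so none was a copy.

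The 37 gene lists were also fixed in advance. Members were counted by direction over all genes tested and adjusted over the list alone. Lists were tested with camera at a preset correlation of 0.01, and as alternatives with an estimated correlation and with fry. At the preset correlation 14 lists passed, 9 up and 5 down. With an estimated correlation camera passed 0 (lowest adjusted p = 0.130), and 4 at an unadjusted p under 0.05. fry, which does not compare a list with other genes, passed 15. Genes named follow a rule fixed in advance: Atf3, 7 fixed genes, the 12 higher and 12 lower called genes with the largest change, and up to 4 members of each list with the smallest p. The 24 needed a mean of at least 1 count per 1e+06 and no overlap of the groups, and provisional and small-RNA symbols were counted and not named. Of the genes the rule names, 6 are not reported, and none was put in their place; they stay in all counts and set tests, but not in the search for single libraries apart. Scd1, Mki67, Ccne1, Cyp17a1, Cyp3a41a, C6, Cyp4a12b, Mir6236, Rn45s and genes named only in the closing part were chosen after their values were seen. A comparison by the authors was not analysed here.

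The procedure was tested on simulated data for 13301 genes with 200 changed, using the step and spread of these libraries. It recovered 32.8% of genes changed 1.5-fold, 68.7% at 2-fold and 93.9% at 4-fold, and 3 of 133 calls were false. The real data gave 2819 calls, so the adjusted threshold was stricter on p in the simulation. Genes were drawn independently, without shifts shared by the genes of a library. These rates may therefore not hold for the real data. Library measures were compared by exact two-sided permutation over 70 assignments, adjusted over 9 measures. Depth was estimated as the column sum over the most frequent low value, a rough figure because the values include a correction for transcript length. Coordinates and the share of 31-base stretches found in transcripts of other genes come from GENCODE vM21 for mm10, matched by symbol, which may differ from the annotation the authors used. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and figures. Alternatives covered scaling, filters, pseudocounts, robust variance, library weights, TPM, a fold threshold and leaving out each library. DESeq2, voom and voom weights were not run, since the files hold no counts.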

Results

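RNA from mouse liver was sequenced 8 weeks after C57BL/6J mice, 10 weeks old, received an adeno-associated virus (AAV8) into a vein. The virus was named for ATF3 (ATF3 group) or for no gene (Null group), and ALB in both names was taken as the albumin promoter. The question was which liver genes ATF3, a stress-induced transcription factor, regulates. There were 4 libraries in each group, 8 in all, although the design text states 8 mice per group. The labels do not say whether each library came from 1 mouse, so the p-values measure the spread between these libraries. The deposited normalized counts summed to between 23.9 M and 28.4 M per library. From the most frequent low value of each library, depth was roughly estimated at 23.5, 48.5, 17.2 and 18.2 M reads for Null 1 to 4. The estimates for ATF3 1 to 4 were 48.5, 22.9, 24.6 and 22.5 M reads. Log values correlated across genes, which are not independent replicates, with r of 0.959 to 0.988 within groups and 0.932 to 0.959 between them.

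Atf3 transcripts were more abundant in every ATF3 library than in any Null library. Null 1 to 4 held 24.2, 22.5, 24.5 and 20.3 normalized counts of Atf3. ATF3 1 to 4 held 5611, 5886, 7053 and 6722, a log2 change of 8.05 (SE 0.11, adjusted p = 5.6e-11). Transcripts of the delivered and the endogenous gene (chromosome 1, 191170296 to 191218039, in mm10) cannot be separated in these values.

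Of 13301 genes tested with limma, 1513 rose and 1306 fell at an adjusted p under 0.05. Of these, 510 and 333 changed by at least 1 on the log2 scale, on which all changes are given. The groups did not overlap for 2621 of the 2819 called genes and for 26.3% of all tested genes, where chance gives 2.86%. The first principal component carried 57.7% of the variance and parted the groups, and Null 4 lay apart on the second, which carried 16.7%. Without ATF3 3, the number of lower genes was 851. The deposited TPM gave another balance, with 440 higher and 76 lower genes, and moved the median change of all genes from 0.00681 to 0.68. With TPM, the sign of Abcb11, Apoa1, Gys2, Shmt2, Xbp1, Bst2, C8b, Rora, Foxa3, Nr1i2, Nr1i3, F9, Ptprb, Rgs5, Rps24 and Rpl8 turned among the genes reported, and none of them was called. The medians of the lists called down became 0.0865 (male-biased), 0.73 (complement), 0.63 (hepatocyte markers), 0.60 (clock) and 0.69 (ribosomal), around that shift or below it. The shift was not equal in all lists, and the bile acid synthesis median moved from 0.00544 to 0.995 with 1 added to the TPM. It was 1.01 with 0.1 added and 0.77 with 10 added, against 0.93 and 0.23 for all genes. The inequality between lists thus varied with the value added. With TPM rescaled by median of ratios, the medians of the lists called down were -0.86, -0.27, -0.37, -0.21 and -0.28 in the same order. The median of all genes was then 0.00315.

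**Figure D1:**
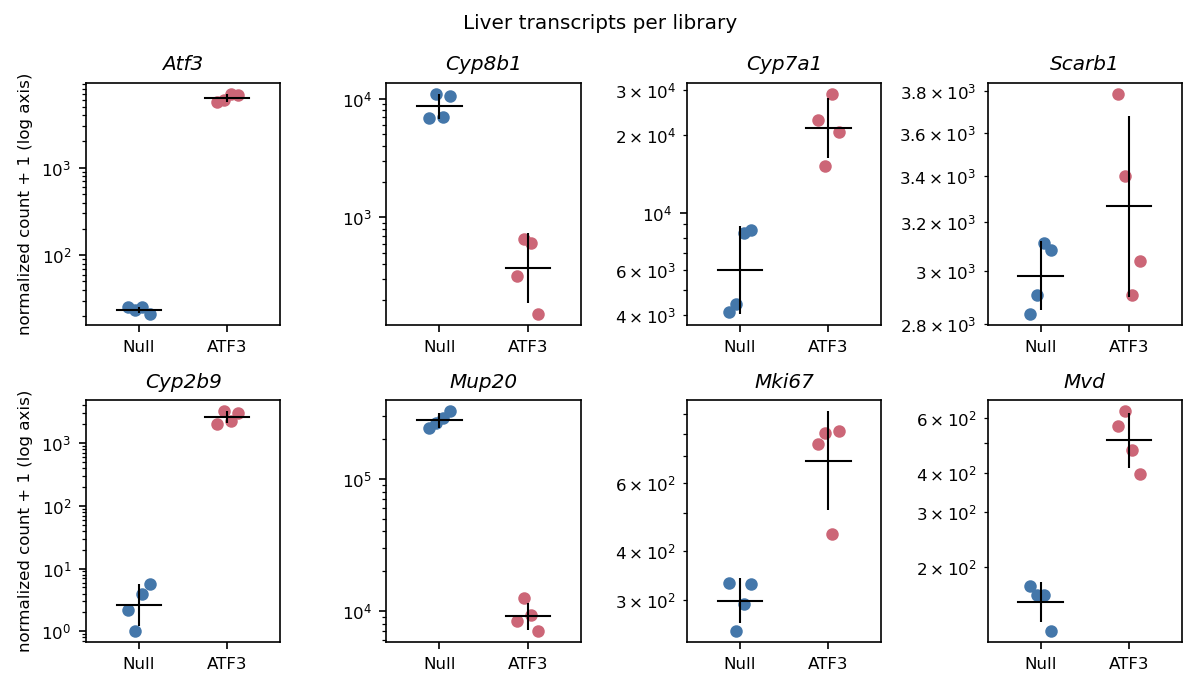
Normalized counts plus 1 (log axes) of 8 genes in the 4 Null and 4 ATF3 libraries. Each dot is 1 library, horizontal lines are means and vertical lines 1 SD, both of log2 values, and Atf3 is higher and Cyp8b1 lower in every ATF3 library.

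Cyp8b1, the sterol 12-alpha-hydroxylase, fell. Its normalized counts were 8818 ± 2180.2 in Null and 432 ± 239 in ATF3 (SD, n = 4 each; log2 change -4.53, SE 0.41, adjusted p = 3.94e-05). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose, with 6350.1 ± 2409.6 in Null and 21967 ± 5732 in ATF3 (SD, n = 4 each; log2 change 1.83, SE 0.28, adjusted p = 0.00109). Abcb11, the bile salt export pump gene, fell by 0.37 (SE 0.10, adjusted p = 0.0291). The apolipoprotein gene Apoa1 fell by 0.46 (SE 0.15, adjusted p = 0.0494). Scarb1, the HDL receptor gene, did not pass, with 2984 ± 135 in Null and 3284 ± 396 in ATF3 (SD, n = 4 each; log2 change 0.13, SE 0.10, adjusted p = 0.394). The cholesterol exporter gene Abca1 did not pass either, at -0.36 (SE 0.12, adjusted p = 0.0611). The Abcb11 call was lost without ATF3 1, ATF3 2, ATF3 3, ATF3 4, Null 2 or Null 3 (adjusted p from 0.0555 to 0.0715). The Apoa1 call was lost without ATF3 1, ATF3 2, ATF3 3, ATF3 4, Null 1, Null 2 or Null 3 (adjusted p from 0.0613 to 0.134). Abca1 passed without ATF3 1 or Null 4 (adjusted p from 0.0232 to 0.027).

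In mm10, Cyp8b1 lies on chromosome 9, 121914356 to 121916305, and Cyp7a1 on chromosome 4, 6265612 to 6275633. Scarb1 lies on chromosome 5, 125277087 to 125341094, and Abcb11 on chromosome 2, 69238282 to 69342616. The position of Abca1 is chromosome 4, 53030787 to 53159895, and that of Apoa1 is chromosome 9, 46228580 to 46230466.

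In the bile acid synthesis list, 5 of 16 tested members rose and 4 fell, or 6 and 5 adjusted over the list alone. The bile acid synthesis list did not pass the camera test (adjusted p = 0.856). Baat, which conjugates bile acids, fell by 1.38 and Akr1d1, a steroid 5-beta-reductase gene, rose by 1.21. In the bile acid transport and sensing list, 4 of 16 tested members rose and 6 fell, or 4 and 8 adjusted over the list alone. The bile acid transport and sensing list did not pass the camera test (adjusted p = 0.397). The uptake transporter gene Slco1a1 fell by 2.88 and Slco1a4 rose by 2.11, while the sterol transporter genes Abcg5 and Abcg8 rose by 1.24 and 0.98. In the lipoprotein metabolism list, 6 of 27 tested members rose and 4 fell, or 9 and 5 adjusted over the list alone. The lipoprotein metabolism list did not pass the camera test (adjusted p = 0.151). The lipoprotein metabolism set test passed without Null 4 (adjusted p = 0.0407). Apoa4 rose by 5.20, Apoc3 rose by 1.25, Apoc2 rose by 1.02 and Apom fell by 1.06.

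Genes of cholesterol synthesis moved up. In the cholesterol synthesis list, 18 of 22 tested members rose and 0 fell, or 18 and 0 adjusted over the list alone. The cholesterol synthesis list passed the camera test (direction up, adjusted p = 9.14e-10), but not with an estimated correlation (adjusted p = 0.203). Mvd, Fdps, Pmvk and Hsd17b7 rose by 1.72, 1.54, 1.38 and 1.19. In the fatty acid oxidation list, 18 of 28 tested members rose and 1 fell, or 18 and 1 adjusted over the list alone. The fatty acid oxidation list passed the camera test (direction up, adjusted p = 4.09e-06), but not with an estimated correlation (adjusted p = 0.475). The acyl-CoA thioesterase gene Acot2 rose by 2.69, Vnn1 rose by 0.94, and the regulators Ppargc1a and Creb3l3 rose by 0.77 and 0.64. In the fatty acid and triglyceride synthesis list, 7 of 22 tested members rose and 4 fell, or 8 and 4 adjusted over the list alone. The fatty acid and triglyceride synthesis list passed the camera test (direction up, adjusted p = 0.0385), but not with an estimated correlation (adjusted p = 0.747). The fatty acid and triglyceride synthesis set test did not pass without ATF3 3 (adjusted p = 0.0557) or Null 3 (adjusted p = 0.164). The lipogenic regulator gene Srebf1 rose by 1.30, Elovl5 rose by 2.03, Acly rose by 1.29 and Pnpla3 rose by 3.54, whereas Scd1, the stearoyl-CoA desaturase gene, fell by 1.09. In the oxidative phosphorylation list, 1 of 27 tested members rose and 0 fell, or 1 and 0 adjusted over the list alone. The oxidative phosphorylation list passed the camera test (direction up, adjusted p = 0.0405), but not with an estimated correlation (adjusted p = 0.794). The oxidative phosphorylation set test did not pass without ATF3 2 (adjusted p = 0.179), ATF3 3 (adjusted p = 0.0557), ATF3 4 (adjusted p = 0.0614), Null 1 (adjusted p = 0.108) or Null 3 (adjusted p = 0.206). Uqcrc1 rose by 0.37, and Ndufa9 at 0.22, Ndufb8 at 0.29 and Sdhb at 0.25 did not pass. Ndufb8 passed without Null 4 (adjusted p = 0.0194). Sdhb passed without Null 4 (adjusted p = 0.0361).

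In the amino acid catabolism and urea cycle list, 17 of 34 tested members rose and 4 fell, or 18 and 4 adjusted over the list alone. The amino acid catabolism and urea cycle list passed the camera test (direction up, adjusted p = 0.000803), but not with an estimated correlation (adjusted p = 0.747). Asl rose by 1.39, Hpd rose by 1.34 and the glutaminase gene Gls2 rose by 0.99, while Mat1a, which makes S-adenosylmethionine, fell by 1.89. In the glucose and glycogen metabolism list, 5 of 21 tested members rose and 6 fell, or 6 and 7 adjusted over the list alone. The glucose and glycogen metabolism list did not pass the camera test (adjusted p = 0.856). Pfkfb1 and Ppp1r3b rose by 1.57 and 1.41, and the gluconeogenic enzyme gene Fbp1 and the glycogen synthase gene Gys2 changed by -1.32 and -0.67. In the antioxidant and glutathione list, 10 of 27 tested members rose and 6 fell, or 10 and 7 adjusted over the list alone. The antioxidant and glutathione list did not pass the camera test (adjusted p = 0.336). Gsta1 rose by 7.30, Ugdh rose by 1.48 and Srxn1 rose by 1.38, whereas Gstp1 fell by 2.38. In the xenobiotic cytochrome P450 and conjugation list, 10 of 28 tested members rose and 5 fell, or 11 and 6 adjusted over the list alone. The xenobiotic cytochrome P450 and conjugation list did not pass the camera test (adjusted p = 0.0602). The xenobiotic cytochrome P450 and conjugation set test passed without ATF3 3 (adjusted p = 0.0429) or Null 4 (adjusted p = 0.00841). Cyp2c38 rose by 3.48, Fmo1 rose by 1.49 and Cyp2d26 rose by 1.19, while Cyp1a2 fell by 1.48.

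Genes with sex-biased expression in liver moved in opposite directions. In the female-biased liver genes list, 12 of 16 tested members rose and 2 fell, or 12 and 2 adjusted over the list alone. The list holds 25 genes, and the others did not pass the filter on low values. Cyp2b9, Sult2a1, Sult2a2 and Sult3a1 lay under 10 in every Null library and passed that filter only through ATF3. The counts, median and set test of this list thus rest partly on the filter. The female-biased liver genes list passed the camera test (direction up, adjusted p = 9.64e-11), but not with an estimated correlation (adjusted p = 0.13). In the male-biased liver genes list, 2 of 20 tested members rose and 14 fell, or 2 and 14 adjusted over the list alone. The male-biased liver genes list passed the camera test (direction down, adjusted p = 6.86e-09), but not with an estimated correlation (adjusted p = 0.393). Of the female-biased genes, Cyp2a4 had 12.2 ± 3.29 in Null and 3901 ± 806 in ATF3 (SD, n = 4 each), and Ntrk2, a neurotrophin receptor gene, rose by 6.08. The exceptions were Cyp17a1, which fell by 5.99, and Cyp3a41a, which fell by 1.55. Of the male-biased genes, Mup20 had 278856 ± 36752 in Null and 9296 ± 2294 in ATF3 (SD, n = 4 each), Mup21 fell by 5.97 and the nudix hydrolase gene Nudt7 fell by 2.30. The exceptions were C6, which rose by 0.69, and Cyp4a12b, which rose by 0.49. Many of these genes have near-identical copies, and the share of 31-base stretches found in transcripts of other genes was 58.1% for Cyp2a4, 64.5% for Mup20 and 99.8% for Cyp3a41a, so values of such single genes are uncertain. It was 0.574% for Ntrk2 and 0.389% for Nudt7. The median change was 0.95 in the 6 female-biased members with under 10% shared stretches (3 higher, 1 lower), against 4.13 in all 16. For male-biased members it was -0.83 in 10 (1 higher, 7 lower), against -0.92 in all 20.

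The 12 genes chosen for the largest rise were Cyp2b9, Sult2a1, Sult2a7, Sult2a2, Cyp2a4, Atf3, Sult2a3, Gsta1, Sult3a1, Tmeff2, Ntrk2 and Cidec. Cyp2b9 had 2.20 ± 2.04 in Null and 2609 ± 580.5 in ATF3, and Cidec, a lipid droplet protein gene, 56.6 ± 22.0 in Null and 3628 ± 969 in ATF3 (SD, n = 4 each). The sulfotransferase genes Sult2a1, Sult2a7, Sult2a2 and Sult3a1 rose by 9.64, 8.60, 8.56 and 7.21, and Tmeff2 rose by 6.85. Sult2a3 was listed at 0 in the 4 Null libraries and held 147, 207, 344 and 202 normalized counts in ATF3 1 to 4. Cyp2b9, Sult2a1, Sult2a2, Sult2a3, Sult3a1 and Tmeff2 lay under 10 in every Null library and passed the filter on low values only through ATF3. The size of their log2 changes therefore depends on the added 1. The 12 genes chosen for the largest fall were Mup9, Mup16, Mup15, Mup13, Mup19, Mup12, Serpina12, Mup11, Mup14, Sdr9c7, Mup18 and Gvin1. Sdr9c7, a short-chain dehydrogenase gene, had 2364 ± 255 in Null and 26.5 ± 4.32 in ATF3, and Serpina12, the vaspin gene, 962 ± 296 in Null and 10.1 ± 5.08 in ATF3 (SD, n = 4 each). Mup16 was listed at 0 in the 4 ATF3 libraries and held 162, 169.9, 95.7 and 249 in Null 1 to 4. The other Mup genes among the 12 lay between -7.70 (Mup9) and -6.38 (Mup18), and 83.3% (Mup11) to 100% (Mup15) of their 31-base stretches occur in other genes. Gvin1, with 99.7%, held 919, 832, 861 and 2149 in Null 1 to 4 and 358, 0, 0 and 236 in ATF3 1 to 4. Its log2 change was -6.00 (SE 1.84, adjusted p = 0.0422), and it moved to -4.63 without ATF3 2 or ATF3 3, the libraries at 0. The Gvin1 call was lost without ATF3 2, ATF3 3, Null 1, Null 2, Null 3 or Null 4 (adjusted p from 0.0554 to 0.113). Under the same criteria, 50 higher and 45 lower genes carried provisional or small-RNA symbols.

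Cell cycle genes were mostly higher. In the cell cycle list, 25 of 33 tested members rose and 1 fell, or 28 and 1 adjusted over the list alone. The cell cycle list passed the camera test (direction up, adjusted p = 2.67e-12), but not with an estimated correlation (adjusted p = 0.175). The cyclin gene Ccnd1 rose by 2.02, and the replication helicase genes Mcm2, Mcm3 and Mcm6 rose by 1.99, 1.31 and 1.37. Mki67, a proliferation marker, had 299.5 ± 38.7 in Null and 702 ± 177 in ATF3 (SD, n = 4 each). The 1 member that fell was the cyclin gene Ccne1, with 89.2 ± 20.2 in Null and 32.0 ± 12.3 in ATF3 (SD, n = 4 each). In the p53 target list, 7 of 20 tested members rose and 0 fell, or 9 and 0 adjusted over the list alone. The p53 target list passed the camera test (direction up, adjusted p = 0.000379), but not with an estimated correlation (adjusted p = 0.13). The cell cycle inhibitor gene Cdkn1a rose by 2.15, Tnfrsf10b rose by 2.22, Aen rose by 1.03 and Ccng1 rose by 0.99.

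In the integrated stress response list, 1 of 25 tested members rose and 5 fell, or 1 and 5 adjusted over the list alone. The integrated stress response list did not pass the camera test (adjusted p = 0.191). Chac1, Trib3 and Shmt2 changed by -4.35, -2.20 and -0.94, but Psat1 rose by 1.37. In the ER chaperones and unfolded protein response list, 3 of 19 tested members rose and 1 fell, or 5 and 1 adjusted over the list alone. The ER chaperones and unfolded protein response list passed the camera test (direction up, adjusted p = 0.0408), but not with an estimated correlation (adjusted p = 0.794). The ER chaperones and unfolded protein response set test did not pass without ATF3 3 (adjusted p = 0.153), ATF3 4 (adjusted p = 0.078), Null 1 (adjusted p = 0.0589) or Null 4 (adjusted p = 0.117). Creld2 rose by 1.71, Manf rose by 0.97, Hspa5 rose by 0.70 and Xbp1 fell by 0.40. The Hspa5 call was lost without ATF3 3, ATF3 4, Null 1 or Null 3 (adjusted p from 0.0654 to 0.0947). The Xbp1 call was lost without ATF3 4 (adjusted p = 0.0579). In the AP-1 and immediate early list, 1 of 15 tested members rose and 2 fell, or 1 and 4 adjusted over the list alone. The AP-1 and immediate early list did not pass the camera test (adjusted p = 0.358). Fosl2 and Junb changed by -1.21 and -1.09, Klf6 rose by 0.45, and Egr1 was at -1.41 (SE 0.46, adjusted p = 0.0545). Egr1 passed without Null 4 (adjusted p = 0.00158).

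**Figure D2:**
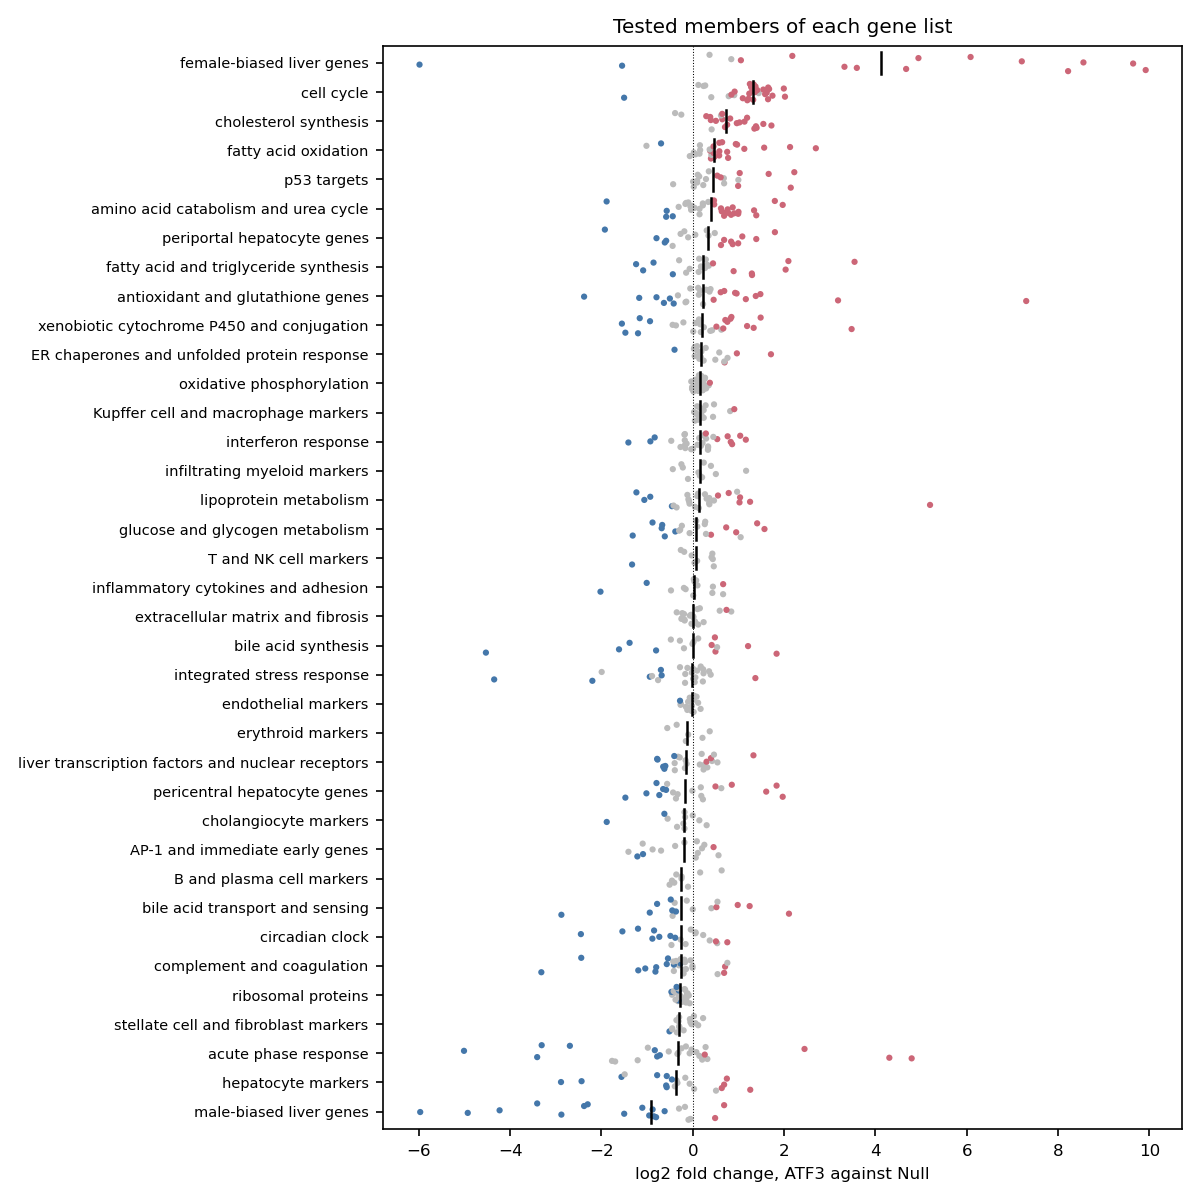
Log2 fold change (x axis, ATF3 against Null) of each tested member of the 37 gene lists (rows); red and blue dots passed the test as higher and lower, grey dots did not, and black lines are medians. The medians lie between -0.92 (male-biased liver genes) and 4.13 (female-biased liver genes). With TPM the male-biased median was 0.0865, against a median of 0.68 over all genes. With TPM rescaled by median of ratios it was -0.86.

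In the acute phase response list, 4 of 27 tested members rose and 7 fell, or 4 and 9 adjusted over the list alone. The acute phase response list did not pass the camera test (adjusted p = 0.101). The acute phase response set test passed without Null 1 (adjusted p = 0.0468). Itih3 fell by 5.01 and the haptoglobin gene Hp fell by 3.41, while Orm3 rose by 4.30 and Serpina3m rose by 2.45. In the complement and coagulation list, 2 of 27 tested members rose and 10 fell, or 3 and 13 adjusted over the list alone. The complement and coagulation list passed the camera test (direction down, adjusted p = 0.000201), but not with an estimated correlation (adjusted p = 0.393). C8a, C8b and Masp1 changed by -3.32, -0.82 and -1.04, and Cpb2, a fibrinolysis inhibitor gene, fell by 2.44. In the hepatocyte marker list, 4 of 20 tested members rose and 8 fell, or 4 and 12 adjusted over the list alone. The hepatocyte marker list passed the camera test (direction down, adjusted p = 0.0142), but not with an estimated correlation (adjusted p = 0.747). Serpina1a, Serpina1b, Asgr2 and F9 changed by -2.89, -2.44, -1.56 and -0.57. In the pericentral hepatocyte list, 5 of 20 tested members rose and 6 fell, or 6 and 7 adjusted over the list alone. The pericentral hepatocyte list did not pass the camera test (adjusted p = 0.856). Oat rose by 1.97 and Lect2 rose by 1.61. In the periportal hepatocyte list, 8 of 20 tested members rose and 4 fell, or 10 and 4 adjusted over the list alone. The periportal hepatocyte list did not pass the camera test (adjusted p = 0.194). Ctsc rose by 1.08 and the urate oxidase gene Uox fell by 1.93.

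In the liver transcription factor and nuclear receptor list, 3 of 24 tested members rose and 6 fell, or 4 and 10 adjusted over the list alone. The liver transcription factor and nuclear receptor list did not pass the camera test (adjusted p = 0.397). Foxa3, Nr1i2 and Nr1i3 changed by -0.65, -0.77 and -0.78. In the circadian clock list, 2 of 19 tested members rose and 8 fell, or 2 and 8 adjusted over the list alone. The circadian clock list passed the camera test (direction down, adjusted p = 0.0405), but not with an estimated correlation (adjusted p = 0.747). The circadian clock set test did not pass without ATF3 4 (adjusted p = 0.0556) or Null 1 (adjusted p = 0.0844). Nfil3, Bhlhe41 and Rora changed by -2.45, -1.54 and -0.85, and Per2 rose by 0.76.

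In the inflammatory cytokine and adhesion list, 1 of 14 tested members rose and 2 fell, or 1 and 2 adjusted over the list alone. The inflammatory cytokine and adhesion list did not pass the camera test (adjusted p = 0.856). The chemokine gene Cxcl1 fell by 2.02, Il1rn fell by 1.01 and Tnfaip3 rose by 0.66, and Vcam1 was at 0.44 (SE 0.16, adjusted p = 0.0727). The Il1rn call was lost without ATF3 1, ATF3 2, ATF3 4 or Null 1 (adjusted p from 0.0523 to 0.0632). Vcam1 passed without Null 4 (adjusted p = 0.0184). In the interferon response list, 7 of 30 tested members rose and 3 fell, or 7 and 3 adjusted over the list alone. The interferon response list did not pass the camera test (adjusted p = 0.388). Mx2 and Bst2 changed by -1.41 and -0.83, while Gbp3 and Rsad2 rose by 1.04 and 0.83. In the extracellular matrix and fibrosis list, 1 of 21 tested members rose and 0 fell, or 0 and 0 adjusted over the list alone. The extracellular matrix and fibrosis list did not pass the camera test (adjusted p = 0.856). Mmp12 at 0.84, Col4a1 at 0.24 and Ctgf at 0.59 did not pass. Ctgf passed without Null 3 (adjusted p = 0.0362).

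Markers of cells other than hepatocytes held few calls. In the Kupffer cell and macrophage list, 1 of 18 tested members rose and 0 fell, or 0 and 0 adjusted over the list alone. The Kupffer cell and macrophage list did not pass the camera test (adjusted p = 0.101). The Kupffer cell and macrophage set test passed without Null 4 (adjusted p = 0.00805). Cd14 rose by 0.91, and Mpeg1 at 0.46, Fcgr1 at 0.28 and Adgre1 at 0.44 did not pass. The Cd14 call was lost without ATF3 4, Null 1 or Null 2 (adjusted p from 0.0569 to 0.0716). In the infiltrating myeloid list, 0 of 11 tested members rose and 0 fell, or 0 and 0 adjusted over the list alone. The infiltrating myeloid list did not pass the camera test (adjusted p = 0.747). Gpnmb was at 1.17 (SE 0.54, adjusted p = 0.156). In the T and NK cell list, 0 of 10 tested members rose and 1 fell, or 0 and 1 adjusted over the list alone. The T and NK cell list did not pass the camera test (adjusted p = 0.856). Cd4 fell by 1.33. In the B and plasma cell list, 0 of 9 tested members rose and 0 fell, or 0 and 0 adjusted over the list alone. The B and plasma cell list did not pass the camera test (adjusted p = 0.388). Cd79a was at -0.51 (SE 0.23, adjusted p = 0.153). In the erythroid list, 0 of 6 tested members rose and 0 fell, or 0 and 0 adjusted over the list alone. The erythroid list did not pass the camera test (adjusted p = 0.856). Alas2 was at 0.37 (SE 0.16, adjusted p = 0.125). At an unadjusted p under 0.05, limma gave 0 infiltrating myeloid, 0 B and plasma cell and 1 erythroid genes.

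In the endothelial list, 0 of 17 tested members rose and 1 fell, or 0 and 0 adjusted over the list alone. The endothelial list did not pass the camera test (adjusted p = 0.388). Ptprb fell by 0.28. The Ptprb call was lost without ATF3 1, ATF3 2, ATF3 3, ATF3 4, Null 1, Null 2 or Null 3 (adjusted p from 0.055 to 0.143). Eng, at -0.27 (adjusted p = 0.102), passed without Null 4 (adjusted p = 0.0448). In the stellate cell and fibroblast list, 0 of 17 tested members rose and 1 fell, or 0 and 0 adjusted over the list alone. The stellate cell and fibroblast list did not pass the camera test (adjusted p = 0.0703). The stellate cell and fibroblast set test passed without ATF3 4 (adjusted p = 0.0236), Null 2 (adjusted p = 0.0313) or Null 4 (adjusted p = 0.034). Rgs5 fell by 0.51. The Rgs5 call was lost without ATF3 1, ATF3 2, ATF3 3, ATF3 4, Null 3 or Null 4 (adjusted p from 0.0533 to 0.102). Ngfr, at -0.36 (adjusted p = 0.105), passed without Null 4 (adjusted p = 0.0396). Pdgfra, at -0.45 (adjusted p = 0.0759), passed without Null 4 (adjusted p = 0.00852). Pdgfrb, at -0.29 (adjusted p = 0.0558), passed without Null 4 (adjusted p = 0.0281). In the cholangiocyte list, 0 of 11 tested members rose and 2 fell, or 0 and 2 adjusted over the list alone. The cholangiocyte list did not pass the camera test (adjusted p = 0.391). Sox9 fell by 1.89. The Sox9 call was lost without ATF3 2, ATF3 3, ATF3 4, Null 1, Null 2 or Null 3 (adjusted p from 0.0534 to 0.0683). In the ribosomal protein list, 0 of 24 tested members rose and 4 fell, or 0 and 4 adjusted over the list alone. The ribosomal protein list passed the camera test (direction down, adjusted p = 0.00022), but not with an estimated correlation (adjusted p = 0.747). Rps24 and Rpl8 changed by -0.36 and -0.31. The Rps24 call was lost without ATF3 1, ATF3 2, ATF3 3, ATF3 4, Null 1 or Null 2 (adjusted p from 0.0537 to 0.0645). The Rpl8 call was lost without ATF3 1, ATF3 3, ATF3 4, Null 1 or Null 2 (adjusted p from 0.0529 to 0.0841).

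Median, mean and camera direction differed in sign for bile acid synthesis (median 0.00544, mean -0.26, test down), glucose and glycogen metabolism (median 0.0743, mean 0.0796, test down), inflammatory cytokines and adhesion (median 0.0288, mean -0.10, test down), pericentral hepatocyte genes (median -0.17, mean 0.0504, test down) and T and NK cell markers (median 0.0666, mean 0.00636, test down). Sharing of 31-base stretches also limits single values of Cyp2b9 (26.1%), Gsta1 (92.9%), Apoc2 (78.8%), Acot2 (37.3%), Fdps (27.9%), Gstp1 (38.5%), Sult2a1 (55.6%), Sult2a2 (74.5%), Serpina1a (65.2%), Serpina1b (44.7%), Serpina3m (34.99%), Mup21 (33.9%), Cyp4a12b (62.9%), Sult2a3 (27.4%), Cyp2c38 (16.6%), Cyp2d26 (15.0%), Sult3a1 (13.8%), Cd79a (12.2%) and Tnfrsf10b (10.8%).

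Library composition was compared by exact two-sided permutation tests, for which 4 against 4 libraries allow no p under 0.0286. Normalized counts summed to 27.4 ± 0.932 M in Null and 25.03 ± 0.877 M in ATF3 (SD, n = 4 each; exact p = 0.0286, adjusted p = 0.129). Major urinary protein genes held 7.95% ± 1.28 of them in Null and 0.591% ± 0.127 in ATF3 (SD, n = 4 each; exact p = 0.0286, adjusted p = 0.129). Neither passed after adjustment over 9 measures, although the groups did not overlap in either. With a floor of 0.0286, a measure can pass this adjustment only if most of the 9 reach the floor. Not passing therefore says little about these differences. Genes at 1 or more numbered 15800 ± 318 and 15742 ± 246 (SD, exact p = 0.8). This cut stands for unequal numbers of reads, as the most frequent low value ranged from 0.493 (ATF3 1) to 1.57 (Null 4). The 20 most abundant genes held 26.9% ± 1.62 and 25.9% ± 0.805 (SD; exact p = 0.314). Haemoglobin genes held 0.0262% ± 0.00934 and 0.0259% ± 0.00768 (SD; exact p = 0.971). Pancreatic acinar transcripts made up 1.38% of Null 1 and at most 0.0129% of the other libraries. Mir6236 and Rn45s made up 5.18% of Null 1 and at most 0.332% of the others.

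**Figure D3:**
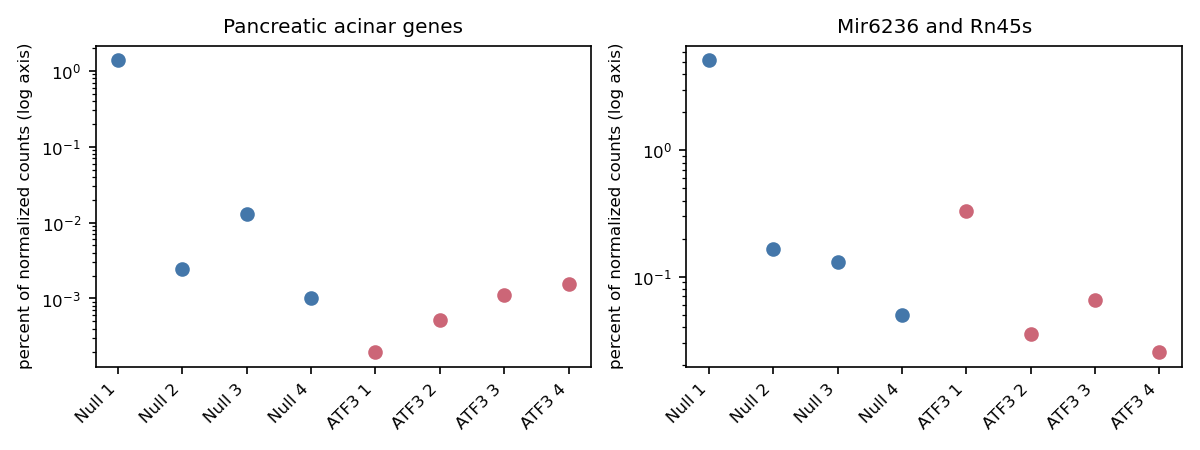
Share of normalized counts (percent, log axes) in pancreatic acinar genes and in Mir6236 with Rn45s for each library; each dot is 1 library. Null 1 is highest in both, at 1.38% and 5.18%.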

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

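Of 340 groups of 4 libraries tested for 1 library far from the other 3, 24 stood out, where chance gives about 1 in 20, or 17.0. The test of depth in Null 1 was chosen after the result was seen. The value in brackets is the gap to the nearest library divided by the group's range. ATF3 1 stood apart in 10 of them. By gene, ATF3 1 was the library apart for Apoc3 (lowest, 0.856), Acly (lowest, 0.839), Fbp1 (lowest, 0.854), Gls2 (lowest, 0.952), Fmo1 (lowest, 0.891), Lect2 (lowest, 0.909), Adgre1 (highest, 0.868). By gene, ATF3 2 was the library apart for Mup19 (highest, 0.849), Ctsc (lowest, 0.960). By gene, ATF3 4 was the library apart for Mup9 (lowest, 0.843), Mup15 (lowest, 0.907), Nfil3 (lowest, 0.909). By gene, Null 1 was the library apart for Col4a1 (lowest, 0.892), Kdr (highest, 0.937). By gene, Null 2 was the library apart for Sult3a1 (highest, 1). It held 0.595 normalized counts against 0 in the other Null libraries, so ties at 0 set this ratio. This case is still counted in the 24. By gene, Null 3 was the library apart for Gys2 (lowest, 0.858), Per2 (lowest, 0.849). By gene, Null 4 was the library apart for Gvin1 (highest, 0.896), Mcm3 (highest, 0.902). For the estimated depth, ATF3 1 was highest in its group (0.917). For the genes detected at 1 or more, ATF3 1 was lowest in its group (0.852). A cut of 1 needs more reads in that library, since its most frequent low value was 0.493. That value was 1.13, 1.04 and 1.10 in ATF3 2 to 4. For the share of Mir6236 and Rn45s, Null 1 was highest in its group (0.977). For the share of Mir6236 and Rn45s, ATF3 1 was highest in its group (0.869). For the pancreatic acinar share, Null 1 was highest in its group (0.991).

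Null 1 held more pancreatic acinar transcripts than any other library, and more Mir6236 and Rn45s. Of 14 acinar genes not looked at before they were listed, 14 were highest in Null 1, and the most abundant of all 24 was Amy2a5 (149561 normalized counts against 1243 in Null 3, the next). A candidate source is pancreatic tissue in the Null 1 sample, and 9 of the 24 genes had a median of at least 10 in the other libraries. The estimated depth of Null 1, 23.5 M reads, lay within the wide range of the others (17.2 to 48.5 M reads). This comparison decides little, since a share of counts is not set by depth. No biological explanation was tested, and whether Mir6236 and Rn45s share the source was not tested.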

How the results depend on the processing

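Weights per library, pseudocounts of 0.5 and 10, rescaled TPM and leaving out Null 1 and Null 4 were chosen after the data were seen. The planned DESeq2, voom and voom-weight tests were not run, since the values are not counts. Rescaling by median of ratios returned the deposited scaling and moved nothing. The main test called 2819, and leaving out 1 library gave 1891 to 3777 (lower genes 851 without ATF3 3 to 1812 without Null 4). Without Null 1 and Null 4 there were 2762, of which 2211 were among the main calls. Weights gave 4401 (2271 higher, 2130 lower), and a log2 change of at least 1 gave 843 (510, 333; list members 149) by construction. Genes called both by an alternative and in the main test had the same direction under each alternative run. TPM with 1, 0.1 and 10 added gave 516, 299, 1020 calls. Their higher and lower genes were 440 and 76, 237 and 62 then 913 and 107, and 76, 55, 120 list members were called. With rescaling of the TPM by median of ratios (1 added) 2828 genes were called, 2713 of them among the main calls. The median change of all genes was then 0.00315, against 0.68 without rescaling. With 1 added, these shifts thus followed the scaling of the TPM per library. Mir6236 held from 0.308% (Null 4) to 89.4% (Null 1) of the TPM and so enters that scaling unequally. Whether it alone accounts for the shifts was not tested. The estimated correlation gave 0 of 37 lists, and TPM with 10 added gave 8, where oxidative phosphorylation turned down (adjusted p = 0.981).

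Rescaled TPM turned the sign of no called gene among those named. Unscaled TPM turned the sign of called genes, with no call in the new direction, at these log2 changes. With 1 added: Abcb11 0.63, Apoa1 0.55, Gys2 0.33, Shmt2 0.0464, Xbp1 0.60, Bst2 0.16, C8b 0.19, Rora 0.10, Foxa3 0.33, Nr1i2 0.19, Nr1i3 0.20, F9 0.42, Ptprb 0.64, Rgs5 0.39, Rps24 0.64, Rpl8 0.69. With 0.1 added: Abcb11 0.64, Apoa1 0.55, Gys2 0.34, Shmt2 0.0649, Xbp1 0.61, Bst2 0.17, C8b 0.19, Rora 0.15, Foxa3 0.36, Nr1i2 0.23, Nr1i3 0.23, F9 0.44, Ptprb 0.72, Rgs5 0.48, Rps24 0.65, Rpl8 0.70. With 10 added: Abcb11 0.53, Apoa1 0.55, Gys2 0.24, Xbp1 0.50, Bst2 0.0609, C8b 0.15, Foxa3 0.18, Nr1i2 0.0359, Nr1i3 0.0744, F9 0.30, Ptprb 0.34, Rgs5 0.12, Rps24 0.54, Rpl8 0.62. The male-biased median was 0.0865 with TPM + 1 against a shift of 0.68 in all genes. With rescaled TPM it was -0.86 against 0.00315. For the named genes, leaving out 1 library ended 2 (Null 4) to 11 (ATF3 4) calls. Differences in library measures, none of which passed, changed sign on leaving out 1 library for estimated depth (-3.51 to 10.01 M reads), genes detected (-166 to 72.3) and haemoglobin share (-0.00349 to 0.00414 percentage points), and the cause was not tested. Of the named genes, unscaled TPM with 1, 0.1 and 10 added ended 60, 63 and 39 calls without turning the sign, and with 10 added it called 1 more. Upper quartile scaling ended the calls of Ptprb, Rgs5 and Rpl8 and called Egr1. Trimmed-mean scaling ended the calls of Apoa1 and Ptprb. The loosest filter ended the calls of Apoa1 and Ptprb. A filter of at least 50 called Pdgfrb. A robust fit ended the calls of Gvin1 and Ptprb. A pseudocount of 10 ended the call of Apoa1. Rescaled TPM ended the call of Apoa1. With the loosest filter the set test passed for xenobiotic cytochrome P450 and conjugation. With at least 50 the set test passed for xenobiotic cytochrome P450 and conjugation and did not pass for ER chaperones and unfolded protein response and circadian clock. Weights added the calls of Abca1, Ndufb8, Sdhb, Egr1, Vcam1, Mmp12, Itgax, Cybb, Eng, Pdgfrb, Pdgfra and Ngfr. Without Null 1 and Null 4, the calls of Apoa1, Gvin1, Manf, Hspa5, Il1rn, Cd14, Ptprb, Rgs5, Rps24 and Rpl8 ended, those of Abca1, Egr1, Vcam1 and Pdgfra were added, the set test passed for lipoprotein metabolism, xenobiotic cytochrome P450 and conjugation, acute phase response, Kupffer cell and macrophage markers and stellate cell and fibroblast markers, and it did not for ER chaperones and unfolded protein response and circadian clock. The simulation, run at 1 setting with 200 changed genes and 4 against 4 libraries, recovered 32.8% of 1.5-fold changes. Whether depth, spread, the number of changed genes or the number of libraries limits this was not tested.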

Other observations

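The gene families and the tests of Y chromosome genes, growth hormone targets, family sums, marker medians and histones were chosen only after the result was seen. All 20 tested major urinary protein genes fell (median -5.93 on the log2 scale). So did 5 of 5 Serpina1 genes, which encode alpha-1-antitrypsins (median -2.89), 5 of 5 Itih genes of hyaluronan-binding inhibitors (median -1.44) and 5 of 6 Nat8 genes (median -2.91). Higher were 4 of 4 Gsta genes (median 2.17), 9 of 14 Cyp2c genes (median 1.001) and 7 of 9 Mcm genes (median 1.28). With TPM rescaled by median of ratios, the medians were -5.59 for major urinary proteins, -2.88 for Serpina1 genes, -1.03 for Itih genes, -1.74 for Nat8 genes, 2.14 for Gsta genes, 0.80 for Cyp2c genes and 0.72 for Mcm genes. Unscaled TPM, which raised the median of all genes, put that of the Itih genes at -0.43 with 1 added and -0.17 with 10 added, and that of the Nat8 genes at -0.91 and -0.42. In the same order, it gave -4.59 and -4.06 for major urinary proteins and -1.87 and -1.86 for Serpina1 genes. It gave 3.10 and 2.65 for Gsta genes, 1.64 and 1.56 for Cyp2c genes and 1.13 and 0.40 for Mcm genes. Lipid droplet genes gave 3 higher and 2 lower of 13. Among the tested Sult2a genes, 4 of 5 rose. Of these, Sult2a1, Sult2a2 and Sult2a3 lay under 10 in every Null library and passed the filter on low values only through ATF3. Sult2a8, the most abundant, was at 27217 ± 6755 in Null and 22594 ± 2155 in ATF3 (SD, n = 4 each, log2 change -0.24, adjusted p = 0.328). The summed Sult2a signal was therefore 27228 ± 6759.8 in Null and 28769 ± 2500.1 in ATF3.

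The number of called genes was compared with that of other splits of the libraries. Only 1 of 35 splits into 4 and 4, the real one, called as many as 2819 genes, and the highest other split called 1. This argues against chance for that count but does not exclude it, since 35 splits allow no share under 1 of 35. The other splits also mix both groups, so a true group difference widens their spread and lowers their calls. For the number of lists chance is not argued against. There, 7 of 35 splits passed at least the real 14 lists with camera at the preset correlation, and the highest other passed 18. By list, the real split had the smallest camera p of the 35 for cholesterol synthesis and female-biased liver genes, among the lists that passed. Of the female-biased list, Cyp2b9, Sult2a1, Sult2a2 and Sult3a1 passed the filter on low values only through ATF3. The rank of that list among the splits thus rests partly on the filter. With the real split counted, the splits that gave as small a p numbered 2 for male-biased liver genes, 3 for fatty acid oxidation, 3 for amino acid catabolism and urea cycle, 3 for p53 targets, 3 for complement and coagulation, 3 for hepatocyte markers, 4 for cell cycle, 5 for circadian clock, 11 for fatty acid and triglyceride synthesis, 11 for ribosomal proteins, 17 for ER chaperones and unfolded protein response and 19 for oxidative phosphorylation.

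Sex-biased genes moved apart in ATF3. Female mice are argued against, since the summed Y chromosome genes differed by -0.0590 on the log2 scale and Xist lay between 0 and 5.68 normalized counts in all 8 libraries. Reads moved between near-identical copies are argued against for the major urinary proteins, whose sum changed by -3.87. The Sult2a sum with Sult2a8, computed first, changed by 0.0794 and decides nothing. Sult2a8 dominates it and shares 0 31-base stretches with the others. The sum without Sult2a8 changed by 9.02, from 11.9 in Null to 6180 in ATF3. Sult2a7, which shares 2 of its 1273 stretches with other Sult2a genes, held 10.6 and 4054 of these. That sum thus mostly follows Sult2a7 and alone cannot argue against moved reads. A Null sum of 11.9 left few reads that could have moved to Sult2a1, at 1216 in ATF3. How reads were divided among Sult2a1, Sult2a2 and Sult2a3 stays open. For the lists as a whole, moved reads stay open too. The median change was 0.95 in the 6 female-biased members with under 10% shared stretches (3 higher, 1 lower), against 4.13 in all 16. For male-biased members it was -0.83 in 10 (1 higher, 7 lower), against -0.92 in all 20. The female minus male difference of these medians with little sharing was 1.78, past the bound of 1 set in advance, but its 95% bootstrap interval, added after that value was seen, spans the bound (-1.96 to 4.96). Lower growth hormone signalling is a hypothesis that stays open, since of its 4 target genes 1, Igfals (-0.50, adjusted p = 0.0459), fell, and Igf1 (-0.19), Socs2 (-0.44) and Cish (-0.76) did not pass.

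Cell cycle genes were higher in ATF3. A rise of non-parenchymal or immune cells as a whole is argued against in the normalized counts, since 93 of their markers had a median change of -0.000907 (SD 0.400) against 1.31 for the cell cycle list. With rescaled TPM these values were 0.00286 (SD 0.231) and 0.57. Unscaled TPM cannot decide this, since its medians depended on the value added and the median of all genes shifted too. With 1 or 10 added the gap lay within the SD. The values were 0.59 (SD 0.374) and 0.96 with 1 added, and 0.16 (SD 0.264) and 0.18 with 10 added. With 0.1 added the gap was wider than the SD, at 0.93 (SD 0.391) and 1.91. The median of all genes was 0.93, 0.68 and 0.23 with 0.1, 1 and 10 added. A single library is argued against too, since at least 21 members were called higher whichever library was left out, and the same 21 were in each of the 8 fits. DNA replication is a hypothesis that stays open: 15 of 42 Hist1 histone genes rose and 2 fell with a camera p of 1.26e-05, but in the exact enumeration of the 35 splits 7, the real one included, gave as small a p, a criterion added after the p was seen. Which cells carried the transcripts was not measured, and a small number of cycling cells of any type stays open.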
